A study of Harpegnathos saltator with 20 samples.

How the data were processed

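RNA was measured in 20 libraries of Harpegnathos saltator brain, 5 for each of d0, d6, d13 and d110. Per the labels, each library came from 3 brains, 5 adoptive colonies of 70 to 100 workers aged 4 to 8 weeks were set up, polyA RNA was fragmented and copied with random primers, and dUTP marked the strand. The labels do not tie a replicate number to a colony, so p-values measure the spread between these samples. The deposited table holds RPKM, reads scaled to the length of the model and to the size of the library, computed by the authors for each library. STAR 2.5.0b is named in the submitters' processing notes. The genome build, the annotation and the read counter are not given in the sources used here, and how reads shared by similar models or overlapping genes were counted is likewise not given, so values of near-identical models are uncertain.

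The table has 19198 rows: 18429 gene models, 43 ribosomal RNA, 542 tRNA, 33 snRNA and 151 miRNA rows, of which 2889 were at 0 in all libraries. The row names carry no gene names or coordinates, and 0 of them were found in the gene name table used here, so gene models are given by ID and length only. For that reason at most 2 IDs that rose and 2 that fell are printed for a comparison, and the gene lists and cell type markers fixed before the data were examined were not tested.

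The deposited RPKM values step in whole reads, which gave the depth of each library and the length of each model. In all 19198 rows the values of all libraries were whole numbers of reads within 0.001 reads, and the steps gave library totals equal to the summed gene-model reads within 0.00029%. After rescaling, 99.2% of gene-model lengths were within 0.01 of a whole number. The library size behind the authors' RPKM was thus the number of reads in gene models, without ribosomal RNA. On simulated data with 13501 rows that had reads in at least 5 libraries, 99.97% were recovered exactly. Depth ranged from 755688 to 12888731 gene-model reads, and the floor of 3 reads at 1 kilobase from 0.233 to 3.97 RPKM. Reads carried no molecular identifiers, so floors and intervals cover counting error only. The lowest chi-square per degree of freedom between libraries of a day was 15.0, so no pair of libraries of the same day agreed within sampling noise.

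Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with an intensity trend, all 20 libraries in 1 fit and the sequencing folder from the labels as covariate (replicates 1 and 2, 3 and 4, and 5). Rows with an RPKM of at least 1 in at least 5 libraries were tested, 10987 in all, and rows with a Benjamini-Hochberg adjusted p under 0.05 were called, separately for each comparison. Fold changes are on the log2(RPKM + 0.5) scale, which understates changes of low models. The 5 comparisons besides d110 vs d0 were d13 and d6 against d0, d13 against d6, d110 against d13 and d110 against d6, and a moderated F-test covered all days. Named models were to be the 15 largest called rises and falls for d110 vs d0 and 5 for each other comparison, with a mean of at least 2 RPKM and at least 4 of 5 libraries beyond the reference mean, reduced to 2 each without names. Exact permutation tests, recovered reads and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Correlations of changes that share the d0 libraries were set beside 100 simulations of unchanged groups and 20 divisions of d0.

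On simulated reads with 200 of 10987 models changed, the d110 vs d0 comparison called 48.2% of 2-fold and 81.4% of 4-fold changes. With the real residuals reshuffled within folders in 40 draws it called 42.4% and 83.1%, with at most 18 false calls, and the d110 vs d6 comparison gave at most 371 false calls.

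The alternatives fixed before the data were examined were other pseudocounts, other filters, median-of-ratios scaling, quantile normalization, no covariate, the replicate number as a block, only the libraries of 2 days, robust empirical Bayes, array weights and leaving out each library. Added after seeing the data were limma voom on the recovered reads, tests without the non-coding rows and 4 models that follow ribosomal RNA, tests without the 4 libraries above 5% ribosomal RNA, a correction for model length and an adjusted p under 0.10, and splits of the libraries within the sequencing folders. The classes of non-coding RNA were grouped by row name after the table was seen. No column of values was left unused.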

Results

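Brains of the ant Harpegnathos saltator were profiled by strand-specific RNA sequencing while workers turned into gamergates, which are mated workers that lay eggs in place of a queen. Each library was made from a pool of 3 whole brains with their optic lobes, and each of the 4 days had 5 libraries. Day d0 was the day on which young workers entered new colonies without a reproductive. Days d6 and d13 were the third and the tenth day of the dominance tournament, at which the ants that duelled most often were taken. Day d110 comprised established gamergates taken 104 to 110 days after the transfer.

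The depth of each library was recovered from the deposited values. Reads in gene models ranged from 5994615 to 10801777 per library at d0, from 4422586 to 9640410 at d6 and from 6054713 to 12888731 at d110. At d13 they ranged from 755688 in replicate 5 to 10423996 in replicate 2. A level of 3 reads in a model of 1 kilobase corresponded to 0.233 RPKM in the deepest library and to 3.97 RPKM in d13 replicate 5, counting error only. Ribosomal RNA took 2.55% ± 1.18 of all reads at d0, 3.14% ± 2.46 at d6, 6.94% ± 8.20 at d13 and 1.52% ± 0.634 at d110 (SD, n = 5 libraries each). The share was 20.6% in d13 replicate 5, 8.51% in d13 replicate 4, 6.33% in d6 replicate 3 and 5.28% in d6 replicate 4, and under 5% in the other 16 libraries.

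**Figure D1:**
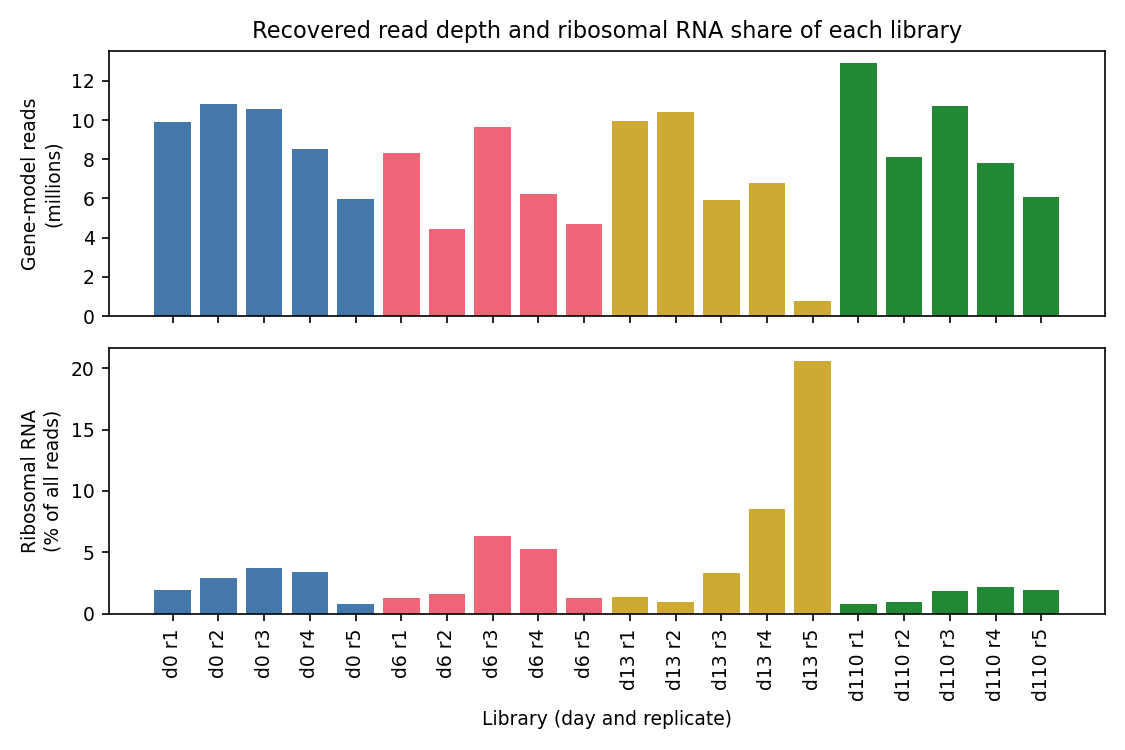
Reads counted in gene models (upper panel) and ribosomal RNA as a percent of all reads (lower panel) in each of the 20 libraries, 1 bar per library, coloured by day (r1 to r5 are the replicates). The library d13 replicate 5 had 755688 gene-model reads and 20.6% ribosomal RNA.

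The first question was how the brains of established gamergates differed from those of workers at the transfer. Time since the transfer differed along with the state, so age and gamergate state cannot be told apart in this comparison. In gamergates 8 gene models were higher and 5 were lower than at d0, of 10987 rows tested with limma. The model Hsal_09096.2, 5454 nucleotides long, rose from 6.83 ± 4.41 RPKM at d0 to 229 ± 190 RPKM at d110 (SD, n = 5 each), and Hsal_04952 rose from 18.9 ± 10.8 to 152 ± 54.6 RPKM. Among the 5 models that fell, Hsal_07585 went from 9.93 ± 5.60 to 1.26 ± 0.515 RPKM and Hsal_05445 from 366 ± 134 to 75.1 ± 36.4 RPKM.

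On the log2(RPKM + 0.5) scale the change of Hsal_09096.2 was 4.78 ± 0.73 (SE), a 27.6-fold difference, with an adjusted p of 0.0192 in limma. Hsal_04952 changed by 3.09 ± 0.52 with an adjusted p of 0.0244, which was 8.52-fold. Hsal_07585 fell by 2.40 ± 0.36 with an adjusted p of 0.0192, and Hsal_05445 fell by 2.33 ± 0.39 with an adjusted p of 0.0244. Over all 36 settings the log2 changes of Hsal_09096.2, Hsal_04952, Hsal_07585 and Hsal_05445 stayed between 4.47 and 5.04, 2.87 and 3.38, -2.82 and -2.11, and -2.65 and -2.06, with adjusted p of at most 0.112. For each of these 4 models all 5 d110 libraries lay beyond the d0 mean in the direction of the change. The direction was also the same within each of the 3 sequencing folders, with differences of 4.31, 5.32 and 4.66 for Hsal_09096.2, of 2.72, 3.77 and 2.48 for Hsal_04952, of -2.04, -2.96 and -1.98 for Hsal_07585 and of -2.39, -2.77 and -1.31 for Hsal_05445. Hsal_07585 was measured from 3 to 11 reads per library at d110. At the days between, Hsal_09096.2 stood at 69.4 ± 71.7 RPKM at d6 and 103 ± 59.0 RPKM at d13, and Hsal_05445 at 222 ± 61.7 and 95.4 ± 62.3 RPKM (SD, n = 5 each). Hsal_09096.2 had a mean of 152 RPKM at d110 without d110 replicate 3 and of 45.4 RPKM at d6 without d6 replicate 3. The 13 called models were all changed more than 2-fold, with a median of 3.45-fold. None of the 33 ribosomal RNA, 104 tRNA, 27 snRNA and 13 miRNA rows tested passed limma in this comparison, with 1, 6, 3 and 3 of them at an unadjusted p under 0.05. Over all rows 2587 (23.5%) had an unadjusted p under 0.05, and at an adjusted p under 0.10 the count was 501, of which 184 were higher and 317 lower.

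The limma count of 13 was 0 when any of d0 replicates 1, 3 and 4 or d110 replicates 1, 3 and 4 was left out, 2 without d0 replicate 5, 6 without d110 replicate 2 and 8 without d110 replicate 5, and it was 563 without d0 replicate 2, 381 without d13 replicate 3 and 30 without d13 replicate 4. All 4 named models lost the call in each of the 6 fits with a count of 0. Hsal_09096.2, Hsal_04952 and Hsal_05445 also lost it without d0 replicate 5, and Hsal_05445 without d110 replicate 2. Hsal_04952 lost it with no covariate (adjusted p 0.0592 in limma) and with the replicate number as a block, settings that gave 5 calls each. Other settings gave 38 (quantile normalization), 819 (only the libraries of the 2 days), 2929 (array weights), 22 (limma voom) and 32 (without the 4 libraries above 5% ribosomal RNA).

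**Figure D2:**
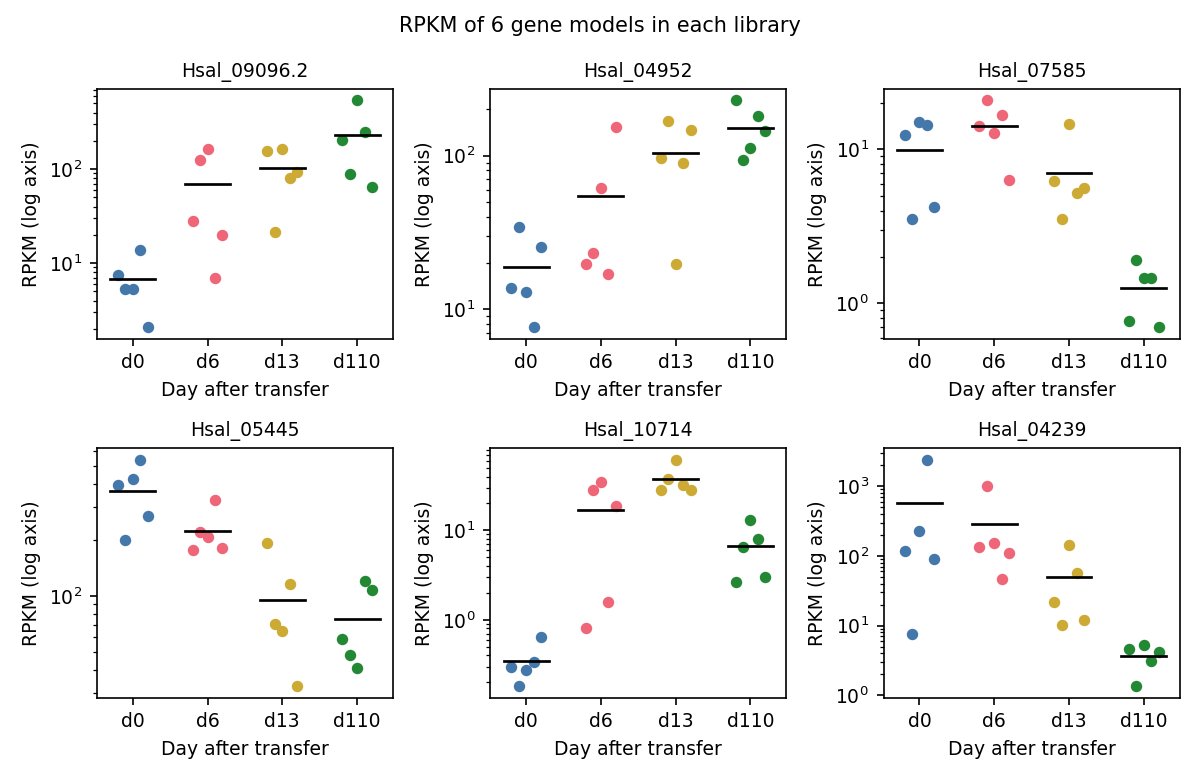
RPKM of 6 gene models (log axis) in each library by day, with 1 point per library (n = 5 per day) and a black line at the day's mean. Hsal_09096.2 and Hsal_04952 were higher and Hsal_07585 and Hsal_05445 lower at d110 than at d0, Hsal_10714 was higher at d13 than at d0, and Hsal_04239 was lower at d110 than at d6.

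The second question was what had changed late in the tournament. Duelling, the choice of the ants that duelled most often and time since the transfer cannot be told apart in this comparison. At d13, 2 gene models were higher than at d0 and none was lower in limma. Hsal_10714 was nearly silent at d0, at 0.347 ± 0.178 RPKM, and reached 37.6 ± 14.1 RPKM at d13 (SD, n = 5 each). It stood at 16.9 ± 15.5 RPKM at d6 and at 6.63 ± 4.23 RPKM at d110. Hsal_03536 went from 0.0131 ± 0.0293 to 3.46 ± 2.58 RPKM.

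The log2 change of Hsal_10714 from d0 to d13 was 5.45 ± 0.73 (SE) with an adjusted p of 0.00692 in limma, and the differences within the 3 sequencing folders were 5.49, 5.81 and 4.65. Its reads summed to 15 at d0 and 1317 at d13, a ratio of 119 per gene-model read (exact 95% interval 71.8 to 213, counting error only), which the pseudocount compressed to 43.7-fold. Hsal_03536 changed by 2.73 ± 0.43 with an adjusted p of 0.0330 and within-folder differences of 2.34, 2.47 and 4.04. It had 1 read at d0 against 131 at d13, a ratio of 177 with an exact 95% interval from 31.3 to 7053. Its mean over all libraries was under the 2 RPKM asked of named models, and it was named after its values were seen because only 2 models were called. Hsal_10714 was above the d0 mean in all 5 d13 libraries, and so was Hsal_03536. No gene model was called lower in limma, and 474 rows (4.31%) had an unadjusted p under 0.05, no more than unchanged rows would give on average. limma voom on the recovered reads called 0 models, with an adjusted p of 0.0756 for both. Hsal_03536 lost the call, leaving a count of 1, with pseudocount 0.1, quantile normalization, only the libraries of the 2 days or the replicate number as a block. The same held without the libraries rich in ribosomal RNA. It also held without any of d0 replicates 1 to 5, d6 replicates 1, 2 and 5, d13 replicates 2, 4 and 5 or d110 replicate 2. The count was 4 without d13 replicate 1.

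The early tournament was compared with the transfer next, where duelling, the choice of ants and time since the transfer again cannot be told apart. No row was called between d6 and d0 in limma, while 986 (8.97%) had an unadjusted p under 0.05, and limma voom on the recovered reads also called 0. The smallest adjusted p was 0.226. The median change over all rows was -0.17 on the log2 scale. Hsal_10714, called at d13, had 587 reads at d6 against 15 at d0, a ratio of 53.9 (exact 95% interval 32.4 to 96.8, counting error only), but its 5 libraries spread from 0.817 to 35.2 RPKM. Hsal_09096.2 spread from 7.03 to 166 RPKM at d6. The count was 1 without d110 replicate 1 and 3 with quantile normalization.

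Within the tournament, no row was called between d13 and d6 in limma, with 1918 (17.5%) at an unadjusted p under 0.05 and 0 called by limma voom. The smallest adjusted p was 0.166. Hsal_05445 measured 222 ± 61.7 RPKM at d6 and 95.4 ± 62.3 RPKM at d13, and Hsal_04239 measured 290 ± 401 and 49.1 ± 56.3 RPKM (SD, n = 5 each), neither of them called. The means of Hsal_04239 were 111 RPKM without d6 replicate 2 and 25.4 RPKM without d13 replicate 3. Without d13 replicate 3 the count was 594, and it was 1 without d6 replicate 3 or d13 replicate 2 or with array weights.

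Between established gamergates and late duellers no row was called in limma, with 1476 (13.4%) at an unadjusted p under 0.05 and 0 called by limma voom. The smallest adjusted p was 0.215. Hsal_07585 measured 7.04 ± 4.35 RPKM at d13 and 1.26 ± 0.515 RPKM at d110, and Hsal_10714 measured 37.6 ± 14.1 and 6.63 ± 4.23 RPKM (SD, n = 5 each), without passing the test. The medians over the ribosomal RNA and snRNA rows were -1.30 and -1.25 on the log2 scale, and 9 of 33 and 13 of 27 of these rows had an unadjusted p under 0.05. The rows of a class follow its share of reads in each library, so they were not separate results. Ribosomal RNA took 20.6% and 8.51% of reads in d13 replicates 5 and 4, but 1.35% and 0.976% in d13 replicates 1 and 2. At d110 it took 0.766% to 2.16%. The count was 1 without d13 replicate 1 or d13 replicate 2 or with quantile normalization.

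The largest contrast lay between established gamergates and early duellers. In d110 brains 2491 rows were higher and 859 lower than in d6 brains, 3350 in all, of which 1520 differed more than 2-fold. Of the gene models, 2490 were higher and 849 lower. Among the small and structural RNAs 1 tRNA row was higher, and 7 tRNA, 2 snRNA and 1 miRNA rows were lower, while 0 of the 33 ribosomal RNA rows passed limma, with 1 of them at an unadjusted p under 0.05. The 5 d6 libraries included the 2 with 6.33% and 5.28% ribosomal RNA, and no d110 library exceeded 2.16%.

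Hsal_04239 fell from 290 ± 401 RPKM at d6 to 3.72 ± 1.53 RPKM at d110 (SD, n = 5 each), by 5.36 ± 1.03 (SE) on the log2 scale with an adjusted p of 0.0105 in limma, and Hsal_03921 fell from 81.7 ± 115 to 1.73 ± 0.918 RPKM, by 4.48 ± 1.08 with an adjusted p of 0.0114. Hsal_11255 rose from 5.67 ± 5.83 to 26.9 ± 6.42 RPKM, a log2 change of 2.74 ± 0.56 with an adjusted p of 0.0105. Hsal_00623, a model of 98 nucleotides, changed by 2.86 ± 0.80 with an adjusted p of 0.0163, from 1.65 ± 2.67 to 8.67 ± 4.10 RPKM, on 0 to 5 reads per d6 library and 4 to 18 reads per d110 library. All 5 d110 libraries lay beyond the d6 mean for each of the 4. The d6 means of Hsal_04239 and Hsal_03921 rested on d6 replicate 2, without which they were 111 and 30.4 RPKM. The d6 mean of Hsal_11255 was 3.45 RPKM without d6 replicate 5, and that of Hsal_00623 was 0.529 RPKM without d6 replicate 1. The within-folder differences were -6.91, -4.22 and -4.54 for Hsal_04239, -5.57, -3.86 and -3.53 for Hsal_03921, 4.39, 2.05 and 0.81 for Hsal_11255, and 2.31, 2.53 and 4.62 for Hsal_00623.

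The median change of all rows in this contrast was 0.20 on the log2 scale, and the balance of higher and lower rows followed the scaling. As deposited, 74.4% of the called rows were higher. Median-of-ratios scaling gave 1597 higher and 1616 lower, and quantile normalization gave 1737 higher and 1255 lower. The called rows included 73.3% and 73.8% of the 3350 with the same sign under these scalings. The count was 1329 without d6 replicate 2, 1768 without d110 replicate 3, 1986 without d110 replicate 4, 2144 without d6 replicate 4 and 5090 with array weights, and the call of Hsal_00623 ended without d6 replicate 2 at an adjusted p of 0.0571 in limma.

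The rows called between d110 and d6 were followed through the other days. The 2491 higher rows had a median log2 change against d0 of -0.41 at d6, 0.10 at d13 and 0.53 at d110. The 859 lower rows had medians of 0.22, -0.18 and -0.68. Over all rows tested the medians were -0.17, -0.05 and 0.04, so part of the fall at d6 was shared by all rows. These values are as deposited, and other scalings were not followed through the days. Of the higher rows 66 were above d0 at d6, 1749 at d13 and 2473 at d110. These rows were chosen for a low d6 and a high d110, or the opposite, so the d6 and d110 values were not independent of the choice.

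**Figure D3:**
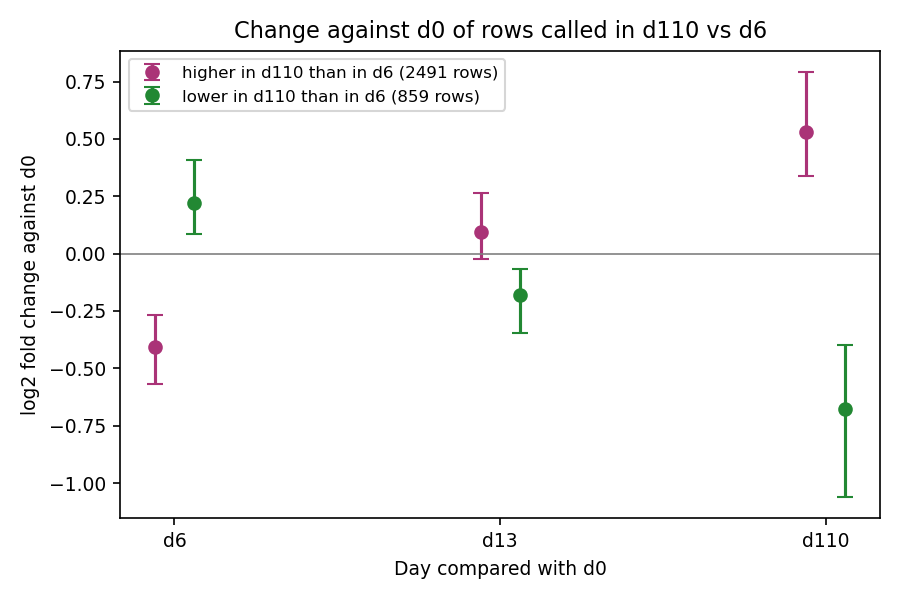
Median log2 fold change against d0 (points) with the lower and upper quartiles over rows (bars) at d6, d13 and d110, for the 2491 rows higher and the 859 rows lower at d110 than at d6. The medians of the higher rows were -0.41, 0.10 and 0.53, and those of the lower rows were 0.22, -0.18 and -0.68. Over all rows tested they were -0.17, -0.05 and 0.04. The called rows were selected on the d6 and d110 libraries.

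Over the 10987 rows tested, the changes against d0 at d6 and at d110 had a correlation across genes of -0.20, where unchanged groups sharing the same d0 libraries gave a median of 0.51 and a range from 0.15 to 0.77. With separate d0 libraries in the 2 contrasts the median was -0.28, from -0.57 to 0.08 over 20 divisions of d0. The covariance was -0.043 against a simulated 0.046, a difference of -0.089. For d13 and d110 the correlation was 0.57, inside the simulated range of 0.063 to 0.75 (median 0.45). It was 0.32 with d0 divided, from -0.050 to 0.55, and the covariance was 0.078 above the simulated one. For d6 and d13 the correlation was 0.15, also inside the simulated range, 0.11 to 0.77 (median 0.50). It was -0.032 with d0 divided, from -0.37 to 0.13, and the covariance difference was -0.024. No model was called both at d13 and at d110 against d0, and independent lists would have shared 0.0015 higher models and 0 lower ones. Genes were not independent replicates in these correlations.

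In a test for any difference between the 4 days, 15 rows passed limma's moderated F-test and 3414 (31.1%) had an unadjusted p under 0.05. The count was 2130 without d13 replicate 3, 1002 without d6 replicate 3, 880 without d6 replicate 5, 707 without d0 replicate 2, 511 without d110 replicate 5, 220 without d13 replicate 4, 16 without d13 replicate 5, and between 0 and 7 without each of the other 13 libraries. It was 5 with no filter, 29 with median-of-ratios scaling, 388 with quantile normalization, 4051 with array weights, 1370 with limma voom and 126 after a correction for model length. In a principal component analysis the first component held 33.6% of the variance, with scores of -10.3 ± 31.3 at d0, -36.0 ± 36.2 at d6, 5.98 ± 39.1 at d13 and 40.3 ± 3.50 at d110 (SD, n = 5 each). The mean score at d110 was above that of d6 by 76.3, of d0 by 50.7 and of d13 by 34.4, each with a two-sided exact permutation p of 0.00794, the smallest that 5 against 5 can give, and 0.0159 after adjustment over the 6 pairs of days. With permutations kept within the sequencing folders the exact p was 0.0278 for each, the smallest that the 72 arrangements can give, and 0.0556 after adjustment, which did not pass. Within the 3 folders the differences between d110 and d6 were 96.8, 83.2 and 21.7, those between d110 and d0 were 44.1, 72.7 and 19.8, and those between d110 and d13 were 23.7, 58.2 and 7.91. The other pairs of days did not pass, with exact permutation p of 0.246 for d6 against d0, 0.476 for d13 against d0 and 0.119 for d13 against d6. The components were computed on the RPKM as deposited. The libraries with the lowest scores had low median-of-ratios factors, 0.828 (d6 replicate 2), 0.746 (d6 replicate 4) and 0.883 (d13 replicate 3). The factors ran from 1.04 to 1.12 at d110, but were 1.13 and 1.15 in d0 replicates 2 and 5, which scored below d110. How much of the first component came from scaling was not tested.

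**Figure D4:**
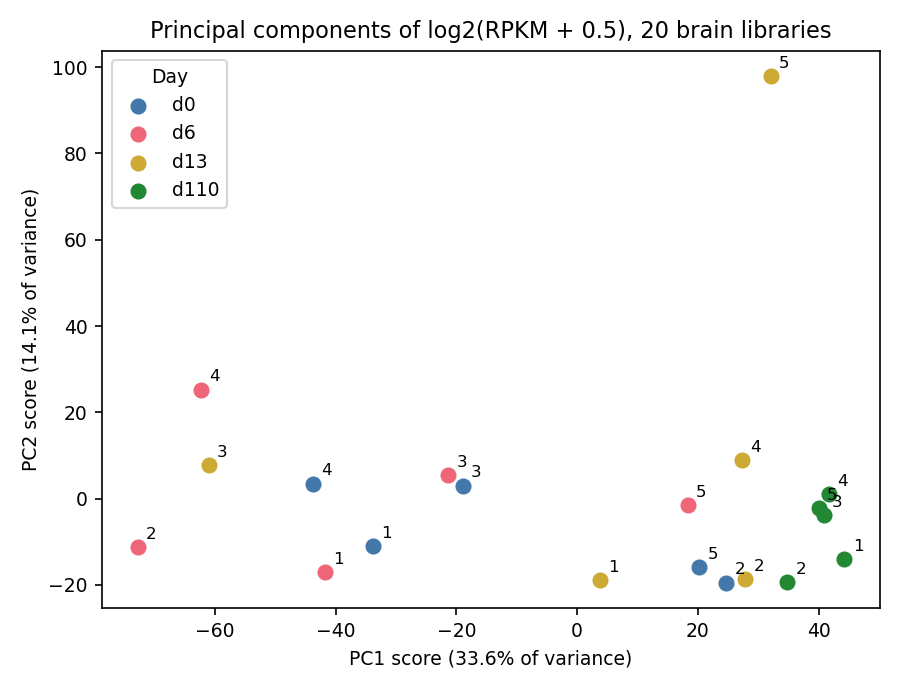
Scores of the 20 libraries on the first component (horizontal, 33.6% of the variance) and the second (vertical, 14.1%) of log2(RPKM + 0.5), with 1 point per library coloured by day and numbered by replicate. The 5 d110 libraries lie between 34.8 and 44.3 on the first component, and d13 replicate 5 lies at 97.9 on the second.

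No share of reads in a non-coding RNA class passed against d0 after adjustment, and the other pairs of days were not tested. The libraries were made from polyA RNA, so these shares need not measure the abundance of the classes in the brain. The smallest exact permutation p that 5 against 5 can give, 0.00794, would not have passed alone over 12 tests. A single clear change could thus have been missed. Over 12 exact permutation tests of ribosomal RNA, snRNA, tRNA and miRNA shares against d0, the smallest two-sided p was 0.0397, for miRNA rows at d110, and its adjusted value was 0.476. These rows held 0.00119% ± 0.00039 of the reads at d0 and 0.000695% ± 0.000182 at d110 (SD, n = 5 each), and the difference was negative in all 3 folders. The miRNA rows rested on few reads, from 11 in d13 replicate 5 to 165 in d0 replicate 3.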

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

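Chosen after the results were seen in this part were the share of calls kept under the 2 other scalings (the scalings themselves were planned), the length correction, the tests without the libraries rich in ribosomal RNA, the thinning tests, the splits within sequencing folders and the test of the models that follow ribosomal RNA. The change against d0 differed between d110 and d6 in 3350 rows in limma, which is the d110 vs d6 contrast itself and not a second result. In a search of 68 groups of 5 libraries for a library far from the others, 3 stood out, where chance gives about 3.4. On the second component d13 replicate 5 scored 97.9, and its gap to the next library was 0.763 of the range of its day. Hsal_03536 had its single d0 read in d0 replicate 1, so the gap was 1 of the range. Hsal_00623 had no read in d13 replicate 5, with a gap of 0.755.

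Many rows were called between d110 and d6, and of 100 splits of these 10 libraries 2 gave as many calls. They were the real one with 3350 and another with 3352 that exchanged d6 replicate 3 and d110 replicate 5. That share was under 5%, without adjustment over the comparisons. The other split crossed the sequencing folders and kept 4 libraries of each day together. Within folders 1 of 36 splits gave as many, the real one, and the highest other gave 1078. The tables argue against scaling, model length, depth and libraries rich in ribosomal RNA as the whole source: 73.3% of the calls held with the same sign under the less favourable of 2 other scalings, 71.3% after a length correction, 91.7% after thinning all 10 libraries to the shallowest and 80.6% without the rich libraries. Scaling did set the balance of directions. After the length correction 1605 rows were higher and 1621 lower. That correction also removed the mean shift of each library, so an effect of length on the balance was not separated from scaling. A difference in the brains between established gamergates and early duellers may therefore underlie the calls, as a hypothesis. Age cannot be told apart from gamergate state in this design. Ovary state and any change in the mix of cells or tissue in the dissection were left open and untested.

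The library d13 replicate 5 stood apart on the second component, 3.88 times as far out as the next library, and had 755688 gene-model reads. With it left out and each of the other 19 thinned alone to that number, with new components, 1 of the 19 reached this ratio (d0 replicate 3, at 4.04 on the third component), so low read depth of a single library may be the source. The other 4 d13 libraries, thinned and projected on the existing components, scored only from -15.8 to 10.9 against 97.9, but those components were computed with d13 replicate 5 and need not hold the counting noise of another library. With all 20 libraries thinned to equal depth it still lay 1.41 times as far out as the next on the second component and 1.63 times on the third (medians of 10 thinnings, lowest 1.20 and 1.29), so low read depth as the whole source stays open. Its ribosomal RNA share of 20.6% as a sign of the cause stays open too, since leaving out the non-coding rows and the models that follow ribosomal RNA kept 10806 of 10987 rows, too many to move the score (97.4), as does damage to the RNA, and no biological explanation was tested for 1 library.

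The reads of 4 gene models of 160 to 824 nucleotides followed ribosomal RNA across the 20 libraries, with correlations from 0.977 to 0.989, where the next highest among 7867 models was 0.764. They took 6.96% of the gene-model reads in d13 replicate 5 and a median of 0.479% over the libraries. Ribosomal RNA reads counted in these models may be the source. A fixed share of ribosomal RNA would give a slope of 1 in log2 reads, and the slope farthest from it was 0.897 with a 95% interval from 0.831 to 0.964, while another was 1.09 with an interval from 1.016 to 1.169. These 2 intervals exclude 1, so this source and a joint change of the transcripts both stay open.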

How the results depend on the processing

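The limma voom, non-coding row, ribosomal RNA library, length and adjusted p of 0.10 settings were chosen after seeing the data. No named model changed sign under any setting. Hsal_04239, Hsal_03921 and Hsal_11255 kept their calls in all 36 settings, Hsal_10714 and Hsal_00623 in 35, Hsal_07585 in 30, Hsal_09096.2 in 29, Hsal_05445 in 28, Hsal_04952 in 27 and Hsal_03536 in 17 of 35. The count for d110 vs d6 stayed within 1.5 times its value in 31 of 36 settings, and that for d110 vs d0 in 16 of 36.

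For d110 vs d0 the 13 calls became 38 with quantile normalization, 5 with no covariate, 819 with only the libraries of the 2 days, 2929 with array weights, 22 with limma voom, 32 without the 4 libraries above 5% ribosomal RNA and 501 at an adjusted p of 0.10, where the last follows from its threshold. For d13 vs d0 the 2 became 1 with pseudocount 0.1, a mean RPKM of at least 5, quantile normalization, only 2 days or without the libraries rich in ribosomal RNA, and 0 with limma voom. For d6 vs d0 there were 3 with quantile normalization, for d110 vs d13 there was 1, and for d13 vs d6 there was 1 with array weights. For d110 vs d6 array weights gave 5090. For any difference between the days the 15 became 5 with no filter, 29 with median-of-ratios scaling, 388 with quantile normalization, 4051 with array weights, 1370 with limma voom, 126 after the length correction and 2034 at an adjusted p of 0.10. Dividing d0 turned the correlation of d6 and d13 changes from 0.15 to -0.032 and lowered that of d13 and d110 from 0.57 to 0.32, through the shared libraries. Apart from these, the cause was not tested.

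With the replicate number as a block the counts were 5 for d110 vs d0, where Hsal_04952 lost the call at an adjusted p of 0.0625, 1 for d13 vs d0, 1 for d6 vs d0, 6 for any difference and 3065 for d110 vs d6. The numbers did not show pairing by the rule set beforehand, since 22 of 30 same-numbered pairs correlated above 0.1 (from -0.18 to 0.53), although 15 of 20 libraries correlated best with their own number and 19 with their own sequencing folder.

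Leaving out each library gave 0 to 563 calls for d110 vs d0, 1 to 4 for d13 vs d0, 0 to 1 for d6 vs d0, 0 to 594 for d13 vs d6, 0 to 1 for d110 vs d13, 1329 to 3826 for d110 vs d6 and 0 to 2130 for any difference. The 563 came without d0 replicate 2, the 594 and the 2130 without d13 replicate 3, the 4 without d13 replicate 1, the 1329 without d6 replicate 2, and the 0 for d110 vs d0 without any of d0 or d110 replicates 1, 3 and 4. Depth limited models with few reads, such as Hsal_00623, Hsal_03536 and Hsal_07585. The gene list tests and their alternatives were not run, since no row name matched a gene name.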

Other observations

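The test of spread in this part was chosen after the result was seen, and so were the models grouped with Hsal_04239; the test of neighbouring numbers was set beforehand for called falls and not for called rises. Hsal_04239, the called model with the largest fall between d6 and d110, varied together with 7 other gene models (correlation of at least 0.95 over the 20 libraries). The 8 models took 1.501% of gene-model reads in d0 replicate 4, 0.641% in d6 replicate 2 and 0.0048% in d110 replicate 2. Their mean log2(RPKM + 0.5) was 6.06 ± 2.69 at d0, 6.22 ± 1.52 at d6, 4.01 ± 1.43 at d13 and 2.02 ± 0.40 at d110 (SD, n = 5 each). Libraries of a day differed widely, from 2.41 in d0 replicate 2 to 9.95 in d0 replicate 4. With d13 replicate 2 at 2.37, a d0 and a d13 library lay inside the d110 range of 1.37 to 2.42. The d110 mean was lower than that of d6 (exact permutation p = 0.00794), d0 (0.0159) and d13 (0.0159), each 0.0265 after adjustment over 5 pairs and 0.0463 with permutations kept within the sequencing folders, but the group was built around a model selected for its fall, so these p-values are too small. In limma all 8 were called lower at d110 than at d6, the contrast in which the model was chosen. In limma 0 of the 8 were called lower than at d0 and 0 lower than at d13, with 8 and 3 at an unadjusted p under 0.05, and limma voom also called 0 in both. Of the 8, 3 had consecutive ID numbers, against at most 2 in 10000 random draws that treated models as independent.

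Hsal_10714 went from 0.347 RPKM at d0 to 16.9 at d6, 37.6 at d13 and 6.63 at d110. The 5 d6 libraries measured 0.817, 28.5, 35.2, 1.56 and 18.6 RPKM. The reads at d110 exceeded those at d0 by a ratio of 21.2 (exact 95% interval 12.6 to 38.3, counting error only).

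On average the d110 libraries lay closer to their day's mean than those of the other days. The mean squared distance per row was 0.173 ± 0.036 at d110, against 0.241 ± 0.031 at d0, 0.372 ± 0.092 at d6 and 0.448 ± 0.234 at d13 (SD, n = 5 each), with an exact permutation p of 0.000645 for d110 against the other 15 libraries, 0.00086 without d13 replicate 5 and 0.0195 with permutations kept within the sequencing folders. Single libraries overlapped, with d110 replicate 4 at 0.225 and d0 replicate 3 at 0.204. The distances within a day shared its mean, so they were not independent and these p-values may be too small. The distances were computed on the values as deposited, without equal depth or another scaling. Brains of established gamergates may be more alike than those of ants on the other days, as a hypothesis. More uniform dissection or library preparation at d110 could give the same exact permutation p of 0.000645.

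Called models were compared with their neighbours in ID number. Of 848 called falls between d6 and d110, 117 were next to another called fall, which equals the 95th percentile of 10000 random relabellings and does not exceed it. Of 2489 called rises 995 were next to another, above the highest of the 10000 relabellings, 887, with a permutation p of 0.0001, the smallest they can give. The relabellings treated models as independent, and neighbours that may share reads were not set apart, so this p may be too small. The rises were those called on the values as deposited, and another scaling was not tried here.

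Other splits of the libraries were counted for each comparison, and their shares were not adjusted over the comparisons. For d110 vs d0, 1 of 100 splits gave 13 calls, the real one, and the highest other gave 1, a share under 5%. These splits crossed the sequencing folders, so splits that exchange libraries only within a folder were added after the counts were seen, 36 for each pair of days. There 1 of 36 gave 13, the real one, with 1 as the highest other, and a share of 1 in 36 is the smallest possible. For d13 vs d0, 4 of 100 gave 2 or more, and the highest other gave 1330, far above the real 2. That share was under 5%, but the split with 1330 points to a structure of the samples, which may include the folders. The count of 2 therefore does not exclude chance. Within folders 1 of 36 gave 2, the real one, and the highest other gave 0. For the test of all days 4 of 100 splits gave 15 or more, with 1820 as the highest other. Of 100 splits within folders 2 did, with 2654 as the highest other, so folders alone do not account for that structure. Both shares were under 5%, but splits far above the real 15 leave chance open. For d6 vs d0, d13 vs d6 and d110 vs d13 the real count was 0, which all 100 splits reach by construction, so these splits say nothing about chance. The highest others there were 1879, 2587 and 13. The split with 2587 calls, which kept to the folders, exchanged d6 replicates 3 and 5 with d13 replicates 3 and 5. Within d13 the scores on the first component ran from -61.1 in replicate 3 to 32.1 in replicate 5, and within d6 from -72.8 in replicate 2 to 18.3 in replicate 5.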
